A study of Homo sapiens with 6 samples.

How the data were processed

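Gene expression was measured by RNA sequencing of total RNA from MCF-7 cells infected with lentivirus that carried hairpin RNA against XIST (4 libraries) or the TurboTRC control hairpin (2 libraries), with RNA taken by TRIzol, per the labels' protocols. The authors aligned reads with STAR 2.4.2a and assigned them to genes with featureCounts 1.4.6-p5, per the submitters' processing notes. The values deposited by the authors are raw counts per gene, with no normalization: a count table of 27598 genes and 6 columns, with whole numbers throughout. The genome build, the annotation release and the strand setting are not given in the sources used here. Gene IDs carry the suffixes of GENCODE annotation lifted to GRCh37, and 26812 of them (97.2%) matched a symbol in the GENCODE 29 reference (GRCh38), which was used for names, chromosomes, gene types, GC content, length, 3' UTRs and positions. In the table, 4909 genes had no count in any library.

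Column names gave the sample name and a number from 1 to 2. Titles give flow cell and lane, but nothing pairs a column with a title. By the titles the control and MCF7-4 are each on a single flow cell, so only the MCF7-2 columns are in doubt. Fits with flow cell as a term, planned before the data were examined, were run under both assignments of these columns, pooled (3 residual degrees of freedom) and by name (2). In the pooled fits the flow cell term leaves only the MCF7-2 library on the control's flow cell to set against the control. The planned comparison within a lane was replaced by all column pairs that can share that lane, as values. Tests, lists, the rule for named genes and most alternatives were also chosen before the data were examined. Titles of a name differ only in flow cell and lane. Libraries of a name were to be summed as runs of a single library unless their extra-Poisson coefficient of variation reached 0.1 for some name, and it reached 0.128, so 6 libraries were kept. The control pair stayed below that limit (0.0745), so by the limit alone its libraries are not shown to be separate. Depth was 33669284 to 44422443 counts per library, and the 2 control libraries limit the precision.

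The pooled comparison used edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood test, Benjamini-Hochberg FDR of 0.05) on 15919 genes, with an extra-Poisson coefficient of variation of 0.188 and 4 residual degrees of freedom. A fit with a term for each of the 3 names (0.111 and 3 residual degrees of freedom) was added after the run check and gave the tests of MCF7-2 and MCF7-4 against the control and against each other. DESeq2 1.42.0 and limma-voom (limma 3.58.1) served as other tools, in R 4.3.3. CPM values are scaled by TMM, and errors are SD between libraries or SE of the fitted log2 fold change. Ratios of the names to the control used log2 CPM with a prior count of 2. In 20 draws from a negative binomial model with no effect, libraries varied only as libraries of the same name do. These draws show what sharing the control libraries produces, but do not cover a control name that stands apart.

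Gene lists (25, of which 24 had tested members) were fixed before the data were examined: X-linked genes that escape or undergo X inactivation, X inactivation machinery, oestrogen receptor and p53 targets, luminal markers, cell division, DNA replication, DNA repair, interferon, ER stress, hypoxia, cholesterol synthesis, heat shock, NF-kB, immediate early, epithelial-mesenchymal transition, ribosomal, mitochondrial, histone and cancer-testis genes, and markers of fibroblasts, basal epithelium, blood and HEK293T. They were tested with camera (correlation 0.01, and estimated) and fry, which compares a list with no other genes, with Benjamini-Hochberg adjustment over lists. Chromosome medians were set against 10000 random lists matched on mean expression. Named genes were, among genes of mean CPM 5 or more, the 12 per direction with the largest smaller change of both names, called genes first, then 4 per direction that differ most between the names, XIST, and up to 4 members per list. Words of 7 bases in 3' UTRs were sought in 14228 genes, each chosen in a part of the genes and tested in the other part by Fisher's exact test (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, figures with matplotlib 3.10.9).

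On simulated data with 200 changed genes, the pooled fit recovered 50.7% of 2-fold and 3% of 1.5-fold changes with 1% false calls, and the tests by name recovered 92.5% (MCF7-2) and 86.6% (MCF7-4) of 2-fold changes with 7.7% and 7.3% false calls. For the tests by name, simulated libraries varied only as libraries of a name do, so these false calls leave out differences between samples. Camera recovered 20 of 20 lists moved by 1.3-fold with 1 false call at a correlation of 0.01, and 18 with 0 false calls with an estimated correlation. Simulated genes varied independently, so these false calls do not cover lists whose genes vary together. Alternatives were scaling, tool, filters, a 1.5-fold threshold, summed libraries, flow cell as a term, column number as a block, each library or name left out, prior counts of 0.5 and 5, and split controls.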

Results

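RNA was sequenced from MCF-7 cells, an oestrogen receptor-positive human breast cancer line, after lentiviral delivery of a short hairpin RNA, a construct that the cell processes into a small RNA that lowers a chosen transcript. A hairpin RNA against XIST, the long non-coding RNA that coats and silences the inactive X chromosome in female cells, gave 4 libraries (group sh_XIST), and the TurboTRC control hairpin gave 2 (group control, sample name MCF7-TRC). The sh_XIST libraries carry 2 sample names, MCF7-2 and MCF7-4, with 2 libraries each, and the labels do not say what the numbers stand for. The labels' protocols also mention exposure to medium, cisplatin or carboplatin without saying which samples received which, so a drug cannot be excluded for any library. Total counts were 42024851 and 40558344 in the control, 44422443 and 38739598 in MCF7-2, and 42032790 and 33669284 in MCF7-4. Between 15222 and 15665 genes had at least 10 counts in a library. Libraries of the same name differed by an extra-Poisson coefficient of variation of 0.0745 (MCF7-TRC), 0.1 (MCF7-2) and 0.128 (MCF7-4), against 0.21 to 0.234 between a library of MCF7-2 and a library of MCF7-4. On the first principal component, with 36.5% of the variance, MCF7-4 lay at 35.9 and 37.6, MCF7-2 at -28.6 and -28.3, and the control in between at -9.01 and -7.62. The second, with 25.2%, set the control (27.55 and 31.59) apart from the 4 sh_XIST libraries (-31.83 to -3.58). Nothing in the labels says that libraries came from separate cultures, so the p-values measure only the spread between these libraries.

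The first comparison asked how far XIST itself was reduced. XIST (ENSG00000229807.10_2) fell 4.12-fold in the sh_XIST group, from 437 ± 5.78 CPM in the control (SD, n = 2) to 106 ± 3.8 CPM (SD, n = 4). It stood at 109 ± 1.07 CPM in MCF7-2 and 103 ± 0.201 CPM in MCF7-4 (SD, n = 2 each), lower than in the control in 4 of 4 libraries. The log2 fold change was -2.04 ± 0.086 (SE; edgeR adjusted p = 0.000119), and MCF7-4 differed from MCF7-2 by -0.088 ± 0.074 on the log2 scale (edgeR adjusted p = 0.45). The gene lies on chromosome X at 73820651 to 73852723, minus strand, in the GRCh38 reference annotation. TSIX, the antisense partner of XIST, had 45 and 27 counts in the control and 10 to 23 in the sh_XIST libraries (log2 -1.07 ± 0.44, edgeR adjusted p = 0.389). The strand setting of the counting is not given in the sources used here, so reads of this overlapping pair cannot be assigned with certainty. JPX and FTX, non-coding neighbours of XIST, lay at 31.7 to 35.2 CPM and 7.31 to 10.2 CPM over the 6 libraries.

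**Figure D1:**
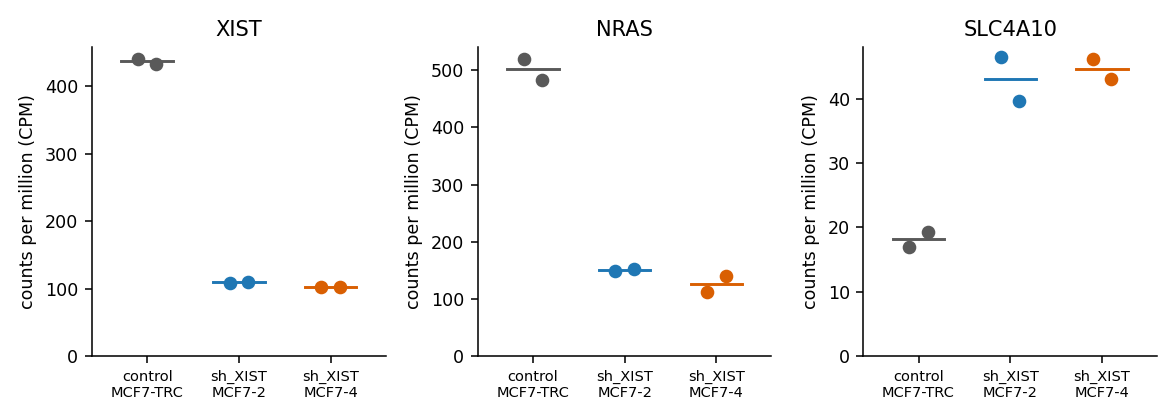
CPM (vertical axis) of XIST, NRAS and SLC4A10 in each library, by sample name, where points are libraries and bars are means of 2 libraries. XIST lay at 441 and 433 CPM in the control and at 103 to 110 CPM in the 4 sh_XIST libraries.

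The second comparison set all 4 sh_XIST libraries against the 2 control libraries, as the series describes. Besides XIST, NRAS fell 3.64-fold, from 501 ± 26.1 to 138 ± 18.3 CPM (SD, n = 2 and 4; log2 -1.86 ± 0.13, edgeR adjusted p = 0.0036). NRAS is a small GTPase of the RAS-MAPK pathway and a known oncogene. SLC4A10, a sodium-coupled bicarbonate transporter, rose 2.41-fold, from 18.2 ± 1.64 to 43.9 ± 3.08 CPM (log2 1.27 ± 0.13, edgeR adjusted p = 0.0499). NRAS (ENSG00000213281.4_1) lies on chromosome 1 at 114704469 to 114716894 and SLC4A10 (ENSG00000144290.16_2) on chromosome 2 at 161424332 to 161985282 (GRCh38 reference annotation). CSDE1, a neighbour of NRAS looked up after the values were seen, had a log2 fold change of 0.086 ± 0.078. XIST, NRAS and SLC4A10 were the 3 genes of 15919 past edgeR's quasi-likelihood test at an FDR of 0.05, 1 higher and 2 lower. At an FDR of 0.1 there were 39 higher and 18 lower genes (17 and 12 with total counts in place of TMM), and at an unadjusted p under 0.05 there were 1911. DESeq2 called 430 genes, these 3 among them, and limma-voom called XIST and NRAS. Without control library 1 or 2 XIST alone passed, with adjusted p of 0.116 or 0.0753 for NRAS and 0.997 or 0.956 for SLC4A10. With flow cell as a term, under either assignment of the MCF7-2 libraries, XIST alone passed (NRAS log2 -1.76 or -1.72, adjusted p = 0.167 or 0.257, and SLC4A10 1.35 or 1.13, adjusted p = 0.245 or 0.388). SLC4A10 also missed the threshold without MCF7-2 library 1 (0.0624) or 2 (0.0831) and without MCF7-4 library 1 (0.114) or 2 (0.143), with DESeq2 size factors in edgeR (0.0505) and at a 1.5-fold threshold (0.492).

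The next comparison took each name against the control, with the spread measured within names, a test added after the difference between the names was seen. Higher under both names were CLEC7A, a lectin receptor for fungal glucans (log2 2.36 ± 0.22 in MCF7-2 and 1.67 ± 0.22 in MCF7-4), RORC, a nuclear receptor (2.01 ± 0.21 and 1.26 ± 0.21), and SERPINA1, the protease inhibitor alpha-1 antitrypsin (1.44 ± 0.19 and 1.11 ± 0.19). CALCR, the calcitonin receptor, rose from 13 ± 0.735 CPM to 28.8 ± 8.01 and 32.1 ± 7.96 CPM (SD, n = 2 each). DDAH1, which degrades asymmetric dimethylarginine, rose by 1.09 ± 0.13 and 1.23 ± 0.13, and SLC1A2, a glutamate transporter, by 1.19 ± 0.12 and 0.97 ± 0.12. Lower under both names were HASPIN, a mitotic histone kinase (-1.10 ± 0.21 and -1.37 ± 0.21), SLC16A1, a lactate transporter (-1.05 ± 0.12 and -1.76 ± 0.13), and the DNA replication factors MCM10 (-0.89 ± 0.13 and -1.16 ± 0.13) and DSCC1 (-0.83 ± 0.16 and -1.04 ± 0.16). E2F2, a transcription factor of cell cycle entry, fell by 0.84 ± 0.18 and 1.14 ± 0.18, and LMNB2, a nuclear lamin, by 0.84 ± 0.15 and 0.84 ± 0.15. MTSS1, PGM2L1, ARHGAP24, PALM3 and the linker histone gene H1-3 also rose under both names, with log2 fold changes of 1.02 to 1.75, and PEX19, DPF1 and B4GALT6 fell, with -1.41 to -0.80. ME2, a mitochondrial malic enzyme, fell in MCF7-2 (-1.01 ± 0.25) and had -0.85 ± 0.25 in MCF7-4 (edgeR adjusted p = 0.0602). Over the 4 pooled libraries none of these genes passed in edgeR, with adjusted p from 0.0906 (DDAH1) to 0.204 (ME2), whereas DESeq2 called each of them.

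In all, MCF7-2 had 634 genes higher and 894 lower than the control, and MCF7-4 had 988 higher and 1189 lower (edgeR, FDR 0.05). Of these, 221 were higher and 198 lower under both names, and 88 went in opposite directions. Independent lists of these sizes would share 39.3 higher and 66.8 lower genes and hold 102.8 opposite ones. Over all 15919 tested genes, called or not, 112 had CPM ratios over 2-fold higher and 67 over 2-fold lower under both names, and 9 had them in opposite directions. More genes passed 2-fold under a single name: 458 in MCF7-2 only and 625 in MCF7-4 only. Across the 15919 genes, which are not independent replicates, the log2 CPM ratios of the names had a Pearson r of 0.351 and a Spearman rho of 0.302, with 60.8% of genes in the same direction. Both names share the control libraries, and 20 simulated draws with no effect gave a mean r of 0.49, 66.6% of genes in the same direction, and means of 0.15 genes called higher and 0 called lower under both. The covariance was 0.074 against 0.0416 simulated. The draws held no difference between names. A shift of the lone control name enters both ratios and cannot be told apart from an effect shared by both sh_XIST names. With a different control library for each name r was 0.147 or 0.13. Of the called genes, 44.3% in MCF7-2 and 48.3% in MCF7-4 differed from the control by less than 1.5-fold. The 1528 called genes of MCF7-2 became 189 or 226 without control library 1 or 2, 568 or 452 without MCF7-2 library 1 or 2, and 2345 or 2312 without MCF7-4 library 1 or 2. The 2177 of MCF7-4 became 454 or 608 without control library 1 or 2.

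**Figure D2:**
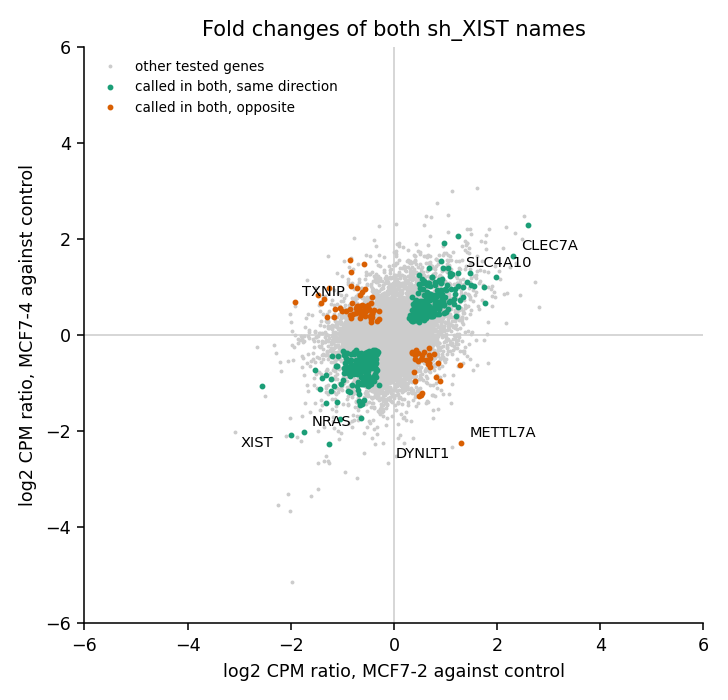
Log2 CPM ratio to the control in MCF7-2 (horizontal axis) and MCF7-4 (vertical axis), where each point is a gene, 15919 in all. Marked points passed edgeR's test under both names, 419 in the same direction and 88 in opposite directions.

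MCF7-4 was then compared directly with MCF7-2, a comparison the control does not enter. METTL7A, a methyltransferase of lipid droplets and endoplasmic reticulum, stood at 27.7 ± 2.33 CPM in the control, 69.3 ± 13.6 in MCF7-2 and 5.99 ± 2.01 in MCF7-4 (SD, n = 2 each). TXNIP, a thioredoxin-binding protein that restrains glucose uptake, went the other way, from 68.5 ± 0.838 CPM in the control to 18.2 ± 3.96 in MCF7-2 and 112 ± 17.9 in MCF7-4. DYNLT1, a dynein light chain, and DCAF12, a substrate receptor of a ubiquitin ligase, fell by 2.67 ± 0.13 and 2.14 ± 0.10 on the log2 scale in MCF7-4, and had -0.12 ± 0.12 and 0.078 ± 0.095 in MCF7-2. TGM2, a transglutaminase, was lower in MCF7-4 than in MCF7-2 (-2.48 ± 0.24), while ZCCHC24 (2.45 ± 0.20), CYP26B1, which degrades retinoic acid (2.39 ± 0.40), and VASH2, a tubulin carboxypeptidase (2.32 ± 0.20), were higher. In all, 1681 genes were higher and 1552 lower in MCF7-4 than in MCF7-2 (edgeR, FDR 0.05), or 366 and 231 over 2-fold. Without MCF7-2 library 1 or 2 the 3233 called genes became 1713 or 1554. By the labels MCF7-4 was sequenced on a single flow cell, the control on the other, and MCF7-2 on both, and the table does not say which MCF7-2 column is on which. With flow cell as a term and MCF7-2 library 1 or 2 on the control's flow cell, called genes numbered 472 or 568 in MCF7-2, 80 or 102 in MCF7-4 and 1695 or 1563 between the names. In these fits XIST had -2.01 or -1.99 in MCF7-2 and -2.11 or -2.07 in MCF7-4, and the DNA replication list had medians of -0.34 or -0.36 and of -0.76 or -0.81. Over the column pairs that can share a lane, MCF7-2 over the control had log2 CPM ratios of -2.02 to -1.97 for XIST and -1.81 to -1.67 for NRAS and 1.04 to 1.45 for SLC4A10, with no test.

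Genes of DNA replication and DNA repair were lower as lists under both names, and cell division genes in MCF7-4, by camera with a preset correlation of 0.01. None of these passed with an estimated correlation (adjusted p = 0.343 and 0.273 with an estimated correlation for DNA replication, 0.343 and 0.263 for DNA repair, and 0.473 for cell division in MCF7-4). All 30 DNA replication and S phase genes had negative fold changes over the 4 pooled libraries (median -0.53), led by CCNE1, the cyclin of S phase entry (-0.99 ± 0.25), ORC1 of the origin recognition complex (-0.90 ± 0.20), the clamp loader subunit RFC4 (-0.75 ± 0.20) and CDC45 of the replicative helicase (-0.71 ± 0.18). Of the 30, 12 fell in MCF7-2 (median -0.35) and 28 in MCF7-4 (median -0.76), and 16 were lower in MCF7-4 than in MCF7-2. Of 30 DNA repair genes, 6 fell in MCF7-2 (median -0.20) and 20 in MCF7-4 (median -0.64). BLM, EXO1 and RAD51, all of homologous recombination, fell under both names (RAD51 by 0.79 ± 0.12 and 0.74 ± 0.12), and PARP1, a poly(ADP-ribose) polymerase, fell by 1.54 ± 0.097 in MCF7-4 and had -0.21 ± 0.094 in MCF7-2. Of 30 cell division genes, 1 fell in MCF7-2 (median -0.046) and 24 in MCF7-4 (median -0.61), and 25 were lower in MCF7-4 than in MCF7-2. MKI67, the proliferation antigen, fell by 0.39 ± 0.088 and 0.89 ± 0.089, and KIF2C, a mitotic kinesin, by 1.22 ± 0.11 in MCF7-4, with -0.037 ± 0.10 in MCF7-2.

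Over the 4 pooled libraries, camera with a preset correlation of 0.01 called 6 of 24 lists at an FDR of 0.05. DNA replication (adjusted p = 2.91e-19), DNA repair (4.38e-11), cell division (2.42e-06) and X inactivation machinery (0.00202) were lower, and replication-dependent histones (0.000162) and mitochondrially encoded genes (0.000809) were higher. None of the 6 was called with an estimated correlation: adjusted p = 0.684 with an estimated correlation for cell division and 0.62 for each of the others. With flow cell as a term, cell division was not called with MCF7-2 library 1 on the control's flow cell. With MCF7-2 library 2 there, the cell division median turned positive and X inactivation machinery was not called. For DNA replication by name, camera gave adjusted p = 6.27e-10 in MCF7-2 and 2.08e-23 in MCF7-4, or adjusted p = 0.343 and 0.273 with an estimated correlation. For DNA repair it gave 0.000373 and 2.93e-16, or adjusted p = 0.343 and 0.263 with an estimated correlation. For cell division it gave 0.753 and 1.3e-18, or adjusted p = 0.943 and 0.473 with an estimated correlation. In the pooled comparison 0 members of the DNA replication, DNA repair and cell division lists passed in edgeR over all genes tested, with 22, 15 and 4 lower at an unadjusted p under 0.05, 10, 7 and 0 lower in DESeq2, and 0 in limma-voom. Adjusted over the list alone, 20, 9 and 0 were lower. Without control library 1 or 2, 0 DNA replication genes were called in MCF7-2 and 19 in MCF7-4 in either case, with medians of -0.33 or -0.36 and of -0.75 or -0.78. Without MCF7-2 library 1 or 2, 2 or 1 were called lower in MCF7-2, and without MCF7-4 library 1 or 2, 19. DNA repair genes called lower in MCF7-2 numbered 0 without either control library, 1 or 2 without MCF7-2 library 1 or 2, and 9 without either MCF7-4 library, and in MCF7-4 they numbered 9 without control library 1. Cell division genes called lower in MCF7-4 numbered 9 or 7 without control library 1 or 2, and the 1 of MCF7-2 was lost without either control library or without MCF7-2 library 1, where the median was 0.052, while camera called the list in MCF7-2 without MCF7-2 library 2 (median -0.12, adjusted p = 0.0257). Between the names, the 16 lower DNA replication genes became 9 without either MCF7-2 library, and the 25 lower cell division genes became 13 without MCF7-2 library 2. Fry, which tests whether the genes of a list move on balance in a single direction and does not compare them with other genes, called X inactivation machinery alone over the pooled libraries (adjusted p = 0.0329), a list that holds XIST itself and had 0.193 without XIST and TSIX. Fry gave 0.193 for DNA replication and DNA repair and 0.562 for cell division. By name it called DNA replication (adjusted p = 0.0361 in MCF7-2 and 0.00944 in MCF7-4), DNA repair (0.0339 and 0.00434) and cell division in MCF7-4 (0.0353).

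**Figure D3:**
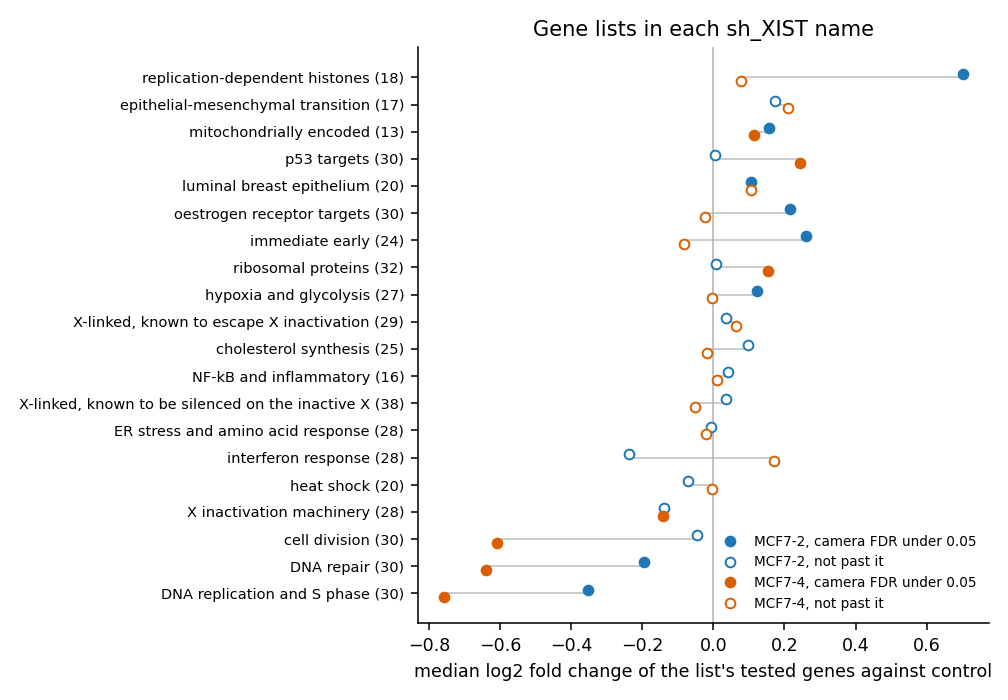
Median log2 fold change against the control (horizontal axis) of each gene list in MCF7-2 and MCF7-4, where filled points passed camera at an FDR of 0.05 with a correlation of 0.01. DNA replication, DNA repair and cell division lay at -0.76, -0.64 and -0.61 in MCF7-4, and replication-dependent histones at 0.70 in MCF7-2.

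Replication-dependent histone genes and oestrogen receptor targets were higher as lists in MCF7-2 by camera (adjusted p = 3.85e-10 and 0.000373, and adjusted p = 0.343 with an estimated correlation for both). Of 18 tested histone genes, 9 rose in MCF7-2 (median 0.70), among them H1-4 (1.41 ± 0.21) and H4C8 (0.87 ± 0.095), and in MCF7-4 3 rose and 3 fell (median 0.079). Of 30 oestrogen receptor targets, 11 rose and 2 fell in MCF7-2 (median 0.22), and 6 rose and 6 fell in MCF7-4 (median -0.023). The MCF7-4 median was -0.133 without MCF7-4 library 1 and 0.047 without MCF7-4 library 2. CCND1, cyclin D1, rose by 0.49 ± 0.069 and 0.49 ± 0.069, the receptor tyrosine kinase RET by 0.89 ± 0.096 and 0.63 ± 0.095, and PKIB, a protein kinase A inhibitor, by 0.70 ± 0.076 and 1.02 ± 0.076, while MYB, a transcription factor, rose by 0.86 ± 0.12 in MCF7-4 and had -0.027 ± 0.12 in MCF7-2. Between the names, 10 of the 18 histone genes were lower in MCF7-4 (camera adjusted p = 1.54e-06, and adjusted p = 0.441 with an estimated correlation), or 5 and 6 without MCF7-2 library 1 and 2. Over the pooled libraries 0 oestrogen receptor targets and 0 histone genes passed in edgeR, with 4 and 8 higher at an unadjusted p under 0.05, 3 and 2 in DESeq2 and 0 in limma-voom, and 3 and 5 were higher adjusted over the list alone. Higher histone genes in MCF7-2 numbered 3 or 5 without control library 1 or 2, and 6 without MCF7-2 library 1. Higher oestrogen receptor targets in MCF7-2 numbered 5 or 6 without control library 1 or 2, and 7 without MCF7-2 library 2, with 0 lower in each case, and 1 was lower without MCF7-2 library 1. In MCF7-4, histone genes called without control library 1 numbered 0 (median -0.071), and without control library 2 there was 1 (median 0.244). Without MCF7-4 library 2, 5 histone genes were higher and 1 lower. Oestrogen receptor targets in MCF7-4 numbered 2 higher and 1 lower without control library 1.

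Targets of p53 were higher as a list in MCF7-4, where 7 of 30 rose and 0 fell (median 0.24, camera adjusted p = 0.00106, and adjusted p = 0.812 with an estimated correlation). BTG2, an antiproliferative factor, rose by 1.52 ± 0.19, TP53INP1, a stress protein, by 1.23 ± 0.11, SESN1 by 1.09 ± 0.16 and CCNG1 by 1.10 ± 0.13. In MCF7-2, 2 of the 30 rose (SESN1 by 0.69 ± 0.16 and CCNG1 by 0.61 ± 0.13) and 2 fell (median 0.005), and 11 were higher in MCF7-4 than in MCF7-2. The 7 higher in MCF7-4 became 4 without either control library and 11 without MCF7-4 library 1, and without MCF7-4 library 2 there were 7 higher and 3 lower. In MCF7-2 called members numbered 0 without either control library or MCF7-2 library 2, 1 higher and 1 lower without MCF7-2 library 1, and 5 higher and 5 lower without either MCF7-4 library. The 11 between the names became 4 without either MCF7-2 library and 6 without either control library or MCF7-4 library 2, and their list's median of 0.28 became 0.13 without MCF7-4 library 2 and 0.42 without MCF7-4 library 1. Fry did not call the list (adjusted p = 0.117 in MCF7-4 and 0.0703 between the names). Over the pooled libraries the list had a median of 0.20 (camera adjusted p = 0.0573), with 2 members higher adjusted over the list alone. Ribosomal protein genes had a median of 0.15 in MCF7-4, where RPS18 rose (camera adjusted p = 0.000569, and adjusted p = 0.812 with an estimated correlation), but RPS18 was not called without a control library or an MCF7-2 library. Luminal breast markers had a median of 0.11 in MCF7-2 (camera adjusted p = 0.00701, and adjusted p = 0.343 with an estimated correlation), with MUC1, a cell surface mucin (0.96 ± 0.091), AR, the androgen receptor (0.53 ± 0.083), and CDH1, E-cadherin (0.39 ± 0.075), higher and GATA3, a luminal transcription factor (-0.28 ± 0.072), lower. The 3 higher became 1 without either control library and 5 without MCF7-4 library 1, and the 1 lower became 0 without either control library or either MCF7-2 library. In MCF7-4 the luminal median was also 0.11, with 3 higher and 2 lower, and camera did not call the list (adjusted p = 0.489). There the counts became 1 and 0 without control library 1, 0 and 0 without control library 2, and 2 and 1 without either MCF7-2 library, and the median was 0.065 without MCF7-4 library 1. CD44, an adhesion receptor on the epithelial-mesenchymal transition list, rose by 0.48 ± 0.11 and 1.07 ± 0.11, on a list with 3 higher and 2 lower in MCF7-2 and 1 higher and 1 lower in MCF7-4. In MCF7-2 that list had 0 higher and 1 lower without either control library and 1 of each without MCF7-2 library 1. In MCF7-4 it had 1 higher and 0 lower without either control library, either MCF7-2 library or MCF7-4 library 1.

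The other lists did not pass camera over the pooled libraries. Their median log2 fold changes were -0.025 for interferon response (adjusted p = 0.828), -0.028 for ER stress and amino acid response (0.623), 0.053 for hypoxia and glycolysis (0.143), -0.049 for cholesterol synthesis (0.835) and -0.096 for heat shock (0.369). NF-kB and inflammatory genes had -0.013 (0.682), immediate early genes 0.076 (0.541), epithelial-mesenchymal transition genes 0.067 (0.541), ribosomal protein genes 0.076 (0.0585), luminal markers 0.088 (0.0513) and oestrogen receptor targets 0.14 (0.101). Markers of other cells had 0.14 for fibroblast (0.26), 0.11 for basal epithelium (0.615), 0.31 for blood (0.615) and 0.076 for HEK293T (0.828). Median and test differed in sign for cholesterol synthesis and HEK293T markers, and median and mean for interferon response (mean 0.017), NF-kB (0.162) and X-linked silenced genes (-0.018). In MCF7-2, immediate early genes (median 0.26, adjusted p = 0.021, and adjusted p = 0.423 with an estimated correlation), hypoxia and glycolysis genes (0.12, adjusted p = 0.0399, and adjusted p = 0.694 with an estimated correlation) and mitochondrially encoded genes (0.16, adjusted p = 0.00162, and adjusted p = 0.698 with an estimated correlation) were higher as lists. In MCF7-4 mitochondrially encoded genes (adjusted p = 0.0368, and adjusted p = 0.812 with an estimated correlation) were higher and X inactivation machinery (adjusted p = 0.00403, and adjusted p = 0.273 with an estimated correlation) was lower, also without XIST and TSIX (adjusted p = 0.0283, and adjusted p = 0.457 with an estimated correlation). In MCF7-2, immediate early genes were not called without MCF7-2 library 1 (median 0.16, adjusted p = 0.126), nor hypoxia and glycolysis genes without control library 1 (0.17, adjusted p = 0.124) or MCF7-2 library 1 (0.13, adjusted p = 0.0817), and the latter had 0.21 without control library 2. Mitochondrially encoded genes were not called in MCF7-2 without control library 1 (median 0.088, adjusted p = 0.125), nor in MCF7-4 without control library 1 (0.033 against 0.12 with all libraries, adjusted p = 0.647) or MCF7-4 library 2 (0.1, adjusted p = 0.0832). Their medians were 0.26 in MCF7-2 and 0.20 in MCF7-4 without control library 2. Fry called heat shock genes, which camera did not, in MCF7-2 (median -0.072, adjusted p = 0.000266), in MCF7-4 (median -0.004, mean 0.026, test downward, adjusted p = 0.0299) and between the names (median 0.038, adjusted p = 0.0107). The heat shock median between the names was 0.079 without MCF7-2 library 1 and -0.003 without MCF7-2 library 2.

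The X chromosome comparison asked whether X-linked genes moved with XIST. MCF-7 is a line reported to have lost its inactive X chromosome, but XIST was not near the floor in the control libraries (441 and 433 CPM). Whether these cells carry an inactive X was not tested. An unchanged X chromosome here therefore does not decide whether XIST silences an inactive X. The 522 tested X-linked genes other than XIST had a median log2 fold change of 0.042 against 0.012 for 15215 autosomal genes (camera adjusted p over chromosomes = 0.975). By name the X median was 0 in MCF7-2 and 0.052 in MCF7-4, against -0.001 and 0.014 for autosomal genes. Genes known to escape X inactivation had a median of 0.077 over 29 members, and genes known to be silenced on the inactive X a median of 0.01 over 38 (camera adjusted p = 0.317 and 0.906). STS, steroid sulfatase and an escape gene, rose in MCF7-2 (1.19 ± 0.13) and had 0.20 ± 0.13 in MCF7-4. PUDP, also an escape gene, rose by 0.45 ± 0.093 and 0.67 ± 0.093, SMC1A, a cohesin subunit, fell by 1.18 ± 0.074 in MCF7-4 and had -0.13 ± 0.073 in MCF7-2, and PRPS1, of nucleotide synthesis, fell by 0.48 ± 0.094 and 0.47 ± 0.094. Escape genes had 4 higher and 1 lower in MCF7-2 and 3 and 2 in MCF7-4, and silenced genes 2 and 4, and 1 and 2. For escape genes the counts in MCF7-2 became 1 and 0 without any single control or MCF7-2 library, and in MCF7-4 they became 0 and 1 without control library 1, 1 and 1 without control library 2, and 1 and 2 without either MCF7-2 library or MCF7-4 library 2. For silenced genes they became 1 and 0 in MCF7-2 without control library 1, 0 and 1 without control library 2 or either MCF7-2 library, and in MCF7-4 0 and 0 without either control library and 4 and 4 without MCF7-4 library 1. Over the pooled libraries 0 X-linked genes other than XIST passed in edgeR, with 44 higher and 34 lower at an unadjusted p under 0.05, 11 higher and 6 lower in DESeq2, and 0 in limma-voom. In MCF7-2, 4.02% of X-linked genes rose and 7.09% fell, against 3.98% and 5.62% of autosomal genes. In MCF7-4, 7.85% rose and 6.9% fell, against 6.18% and 7.57%. X-linked genes other than XIST took 3.29% and 3.28% of counts in the control, 3.18% and 3.2% in MCF7-2, and 3.31% and 3.32% in MCF7-4. Of 28 genes of the X inactivation machinery, 23 had negative fold changes and XIST passed, and the 26 without XIST and TSIX had a median of -0.093 (camera adjusted p = 0.0424, and adjusted p = 0.62 with an estimated correlation).

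**Figure D4:**
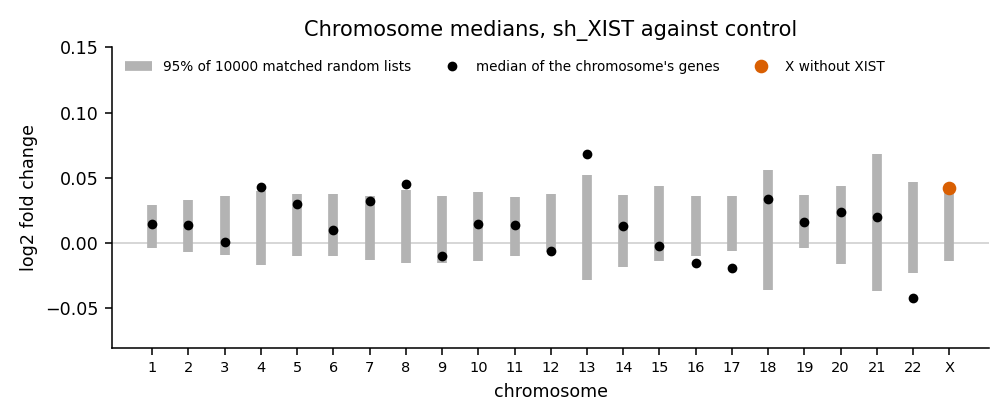
Median log2 fold change of sh_XIST against control (vertical axis) for the tested genes of each chromosome (horizontal axis), with bars that span 95% of 10000 random lists matched on mean expression. The X chromosome without XIST lay at 0.042, with random lists from -0.014 to 0.043. Chromosomes 4, 8, 13, 16, 17 and 22 lay outside their bars, so the bars understate how far chromosomes differ.

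Mitochondrially encoded genes had a median of 0.14 over 13 members, led by MT-ND6 (0.33 ± 0.084), and took 4.07% and 4.49% of counts in the control and 4.58% to 4.72% in the sh_XIST libraries. Without control library 1 the median was 0.054 (camera adjusted p = 0.238), and without control library 2 it was 0.22. Fibroblast markers had a median of 0.0731 CPM in the control and 0.11 CPM in sh_XIST, with COL5A1 the most abundant at 153 CPM in both. Basal epithelial markers had medians of 3.01 and 2.49 CPM, with CDH3 the most abundant at 172 and 199 CPM. Blood markers had medians of 0.0841 and 0.189 CPM, with CD68 the most abundant at 2.24 and 3.05 CPM, and markers of HEK293T, a line used to make lentivirus, 0.243 and 0.215 CPM, with CRABP1 the most abundant at 19.8 and 20.6 CPM. All 6 tested blood markers were higher in MCF7-4 than in MCF7-2 (median 1.07), 2 of them past edgeR's test (CD68 and CD74), while camera did not call the list (adjusted p = 0.0908). Without MCF7-4 library 1 camera called it (median 1.39, adjusted p = 0.00863), and called members numbered 0 without MCF7-4 library 2 or either MCF7-2 library and 1 without either control library. In MCF7-4 against the control camera also called it without MCF7-4 library 1 (adjusted p = 0.0208). The mean centred log2 CPM of these markers was 0.174 and 1.33 in MCF7-4 libraries 1 and 2, against 0.082 and 0.372 for interferon response and 0.085 and 0.273 for p53 targets. In MCF7-4, COL1A2, a collagen (1.04 ± 0.225 CPM), KRT5, a basal keratin (2.41 ± 2.29 CPM), and CD74, the MHC class II invariant chain (3.23 ± 3.58 CPM), rose from low levels, by 3.59 ± 0.87, 3.03 ± 0.75 and 3.05 ± 0.86. They were the called fibroblast and blood markers and 1 of 2 called basal markers of MCF7-4. Without either control library all 3 lists had 0 called. Fibroblast markers also had 0 without MCF7-4 library 1, basal markers 1 without either MCF7-4 library, and blood markers 0 without either MCF7-2 library or MCF7-4 library 2 and 2 without MCF7-4 library 1. The 23 X-linked cancer-testis antigen genes in the table were too low to test, the highest being MAGEC1 at 0.0722 CPM in the control and 0.113 CPM in sh_XIST.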

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

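The tests of the differences between MCF7-4 and MCF7-2, of the XIST level, of the XIST sites with 6-base parts, of a control that stands apart and of reduced XIST were chosen after the result was seen, and the tests of 3' UTR words, flow cell, whole words in XIST, GC content and length were chosen before.

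Each value here is MCF7-4 minus MCF7-2 on the log2 scale, past a test of that difference. Cell division (median -0.615), DNA replication (-0.446), DNA repair (-0.376), replication-dependent histones (-0.617), oestrogen receptor targets (-0.186), cholesterol synthesis (-0.159) and immediate early genes (-0.218) were lower in MCF7-4 as lists. Interferon response (0.384), p53 targets (0.276) and ribosomal protein genes (0.132) were higher. Camera's adjusted p ran from 4.42e-15 (cell division) to 0.0132 (oestrogen receptor targets), and with an estimated correlation none passed (adjusted p = 0.441 to 0.678). Without MCF7-4 library 2 interferon response no longer passed camera (median 0.26, adjusted p = 0.103), nor did ribosomal protein genes without MCF7-2 library 2 (0.078, adjusted p = 0.0829) or immediate early genes without MCF7-2 library 1 (-0.12, adjusted p = 0.066). The median of p53 targets was 0.13 without MCF7-4 library 2 and 0.42 without MCF7-4 library 1, and immediate early genes had -0.34 without MCF7-4 library 2. Blood markers were higher in MCF7-4 as well (median 1.07, 6 of 6 above 0), without passing (adjusted p = 0.0908) unless MCF7-4 library 1 was left out (0.00863), and stood highest in MCF7-4 library 2, as interferon response and p53 targets did. Among genes called under both names, CLEC7A (-0.688), RORC (-0.75), MTSS1 (-0.528), PGM2L1 (-0.73) and SLC16A1 (-0.706) were lower in MCF7-4 and PEX19 (0.525) was higher. METTL7A (-3.54), DYNLT1 (-2.55), TGM2 (-2.48) and DCAF12 (-2.22) were lower in MCF7-4, and TXNIP (2.63), ZCCHC24 (2.45), CYP26B1 (2.39) and VASH2 (2.32) were higher.

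Genes lower in MCF7-4 than in MCF7-2 were weighed first. A different XIST level is argued against by the difference of -0.088 ± 0.074 (SE) between the names, and a flow cell effect by the slope of -0.016 ± 0.013 (SE, 1552 genes) of the difference between the MCF7-2 libraries, which the labels put on different flow cells. Off-target silencing through matches of a hairpin's small RNA in 3' UTRs is a candidate explanation for part of these genes. It assumes that the names carry different hairpins, which the labels do not say. Words chosen in a part of the genes were carried more often by called genes in the other part (weaker p = 2.44e-07, Fisher's exact test, one-sided). The shares were 33% against 24% of genes not called for TCTGAAA and 24.4% against 14.4% for TGAGCTC. Test and shares are not adjusted for 3' UTR length, GC content or expression. Adjusted for these, the MCF7-4 minus MCF7-2 difference shifted in the other part by -0.085 (t = -4.89) and -0.141 (t = -7.30). XIST held 0 sites with whole words, picked over all genes, of both hairpin strands, and its 1 site with 6-base parts of them, AGCTCAACCTATCTGAA, decides nothing with 0.231 expected by chance. TGAGCTC alone occurred 0 times in XIST, and its reverse complement 0 times. A hairpin that matches XIST at every base therefore cannot hold the whole word, though shorter parts of it are not covered.

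Genes lower in MCF7-2 than in MCF7-4 gave the same reading for XIST (-0.088 ± 0.074) and flow cell (slope -0.026 ± 0.016, SE, 1681 genes). Here too a 3' UTR word may account for part of the genes (weaker p = 0.000326, Fisher's exact test, one-sided): AGGGCCA, chosen in either part, was carried in the other part by 25.6% and 20.2% of called genes against 15.5% and 15.3% of genes not called. Adjusted as above, the MCF7-2 minus MCF7-4 difference shifted in the other part by -0.083 and -0.088. For AAGGGCC and TCGAACT, picked over all genes against the control, XIST held 0 sites with whole words of both strands, the test chosen before. AAGGGCC alone occurred 0 times in XIST, and its reverse complement 3 times. The search with 6-base parts, added afterwards, found 1 site, GCCCTTCTCTTCGAACT, where 0.0266 were expected. That value is not adjusted for the several searches made, so a hairpin against that site stays only a possibility. NRAS carries the word TGAGCTC 1 time, TCTGAAA 2 times and AAGGGCC 1 time in its 3' UTR, so an off-target fall of NRAS under both names stays open. These words are common, in 2183, 3547 and 1669 of 14228 genes. Of genes called lower than the control, 70.4% in MCF7-2 carried neither AAGGGCC nor TCGAACT, and 50.6% in MCF7-4 carried neither TGAGCTC nor TCTGAAA. METTL7A, DYNLT1, TGM2 and DCAF12, lower in MCF7-4, each carry TGAGCTC or TCTGAAA. So do TXNIP and VASH2, which were higher there. Of the named genes lower in MCF7-2, CYP26B1 carries AAGGGCC, and TXNIP, ZCCHC24 and VASH2 carry neither AAGGGCC nor TCGAACT. In MCF7-4 against the control, genes with TCTGAAA but not TGAGCTC had a median of 0.003, and genes with neither had 0.029. Genes with both TGAGCTC and TCTGAAA had a median of -0.072 in MCF7-4, and genes with AAGGGCC but not TCGAACT -0.064 in MCF7-2. NRAS had -2 and -1.74. A high NRAS level in the single control name cannot be told apart from an effect of the hairpins.

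DNA replication genes lower than in the control were weighed last. GC content and transcript length are argued against by a median of -0.526 after their adjustment. The 18 members without TGAGCTC, TCTGAAA, AAGGGCC and TCGAACT had a median of -0.541. That argues against direct matches of these words in the list's own 3' UTRs. It does not cover other words or an indirect effect of off-target silencing. A control that stands apart cannot produce the difference between MCF7-4 and MCF7-2 (-0.446), but for the part shared with MCF7-2 (-0.354) it cannot be told apart from a hairpin effect with a single control name. Reduced XIST may contribute, yet the list moved 2.14 times as far in MCF7-4 as in MCF7-2 at like XIST levels, and no library has a hairpin against XIST without reduced XIST, so the effects of hairpin and XIST cannot be told apart. A platinum drug in some of the samples, which the labels leave open, was not tested.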

How the results depend on the processing

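The fits by name, their alternatives, the mean of names, the 2 assignments of MCF7-2 columns to flow cells and the block were chosen after the result was seen, while the other tests were chosen before. For the named genes and called lists, 38 results in all, 587 of 748 alternatives kept the direction and the side of the threshold, 37 no longer passed, 96 passed where the reported value had not, and 28 reversed. XIST had log2 fold changes of -2.09 to -1.99 in the alternatives and passed in each but the fit of 3 summed names (-2.04, adjusted p = 0.506), which has a lone control library assumed to vary like the others and 1 residual degree of freedom. The X chromosome difference stayed within 0 to 0.037 and passed in no alternative, and its sign turned, at 0 after rounding, without both MCF7-4 libraries.

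The 3 genes called over the pooled libraries became 430 in DESeq2, 6 with no filter, 0 with summed names in edgeR (358 at an unadjusted p under 0.05, 4 in DESeq2, 0 in limma-voom), 1 to 3 without a single library, 1908 without MCF7-2, 2314 without MCF7-4, and 1521 for the mean of names. The last 3 measure the spread within names, which was smaller. With flow cell as a term 1 gene was called, XIST, under either assignment of the MCF7-2 columns (1145 or 1429 at an unadjusted p under 0.05, 84 or 119 in DESeq2, 1 in limma-voom). The 6 lists called became 0 with an estimated correlation, 1 with fry, 10 for the mean of names, and 10 or 5 with flow cell as a term. With both MCF7-2 libraries out the histone list (adjusted p = 0.524) and the mitochondrially encoded list (0.052) no longer passed, nor did the cell division (0.758) and X inactivation machinery (0.0675) lists with both MCF7-4 libraries out. With flow cell as a term cell division had adjusted p = 0.0908 with MCF7-2 library 1 on the control's flow cell and reversed to 0.051 with library 2, where X inactivation machinery also missed (adjusted p = 0.0795). Of the genes that differ between the names, METTL7A reversed without both MCF7-2 libraries (-2.22) or library 1 (-0.22 to 0.81 without a single library), in limma-voom (-0.44) and for the mean of names (-0.45), and TXNIP without both MCF7-2 libraries (0.71), library 1 (0.26) or library 2 (0.23; -0.59 to 0.26 without a single library). VASH2 reversed without both MCF7-4 libraries (-1.48), library 1 (-0.21) or library 2 (-0.34), without control library 2 (-0.057; -0.34 to 0.40 without a single library), in limma-voom (-0.36) and for the mean of names (-0.33). Without both MCF7-4 libraries so did ZCCHC24 (-0.86), CYP26B1 (-0.39), TGM2 (0.19) and DCAF12 (0.082). With flow cell as a term the reversed values under the 2 assignments were -1.33 and -1.67 (VASH2), -0.72 and -1.03 (ZCCHC24), -0.053 and -0.86 (CYP26B1), 0.038 and 0.33 (TGM2), and 0.099 and 0.056 (DCAF12).

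The correlation of the names, 0.351, was 0.147 and 0.13 with split controls and 0.209 with library 1 of MCF7-2 and 2 of MCF7-4 alone. Called genes in MCF7-2 (1528) became 2560 with no filter, 57 at a 1.5-fold threshold, 2314 with only the names compared in the fit, and 189 to 2345 without a library. In MCF7-4 (2177) they became 118 at 1.5-fold and 454 to 2270 without a library, and between the names (3233) 291 at 1.5-fold and 1554 to 3056 without a library. Apart from the summed fit, filters, thresholds and left-out libraries, the cause was not tested. Columns share only a number: across genes, deviations of same-numbered libraries had an r of -0.18 (control and MCF7-2), -0.196 (control and MCF7-4) and 0.195 (MCF7-2 and MCF7-4), and a replicate block by column number gave 2 called genes and 6 lists. With flow cell as a term, called genes were 472 or 568 in MCF7-2, 80 or 102 in MCF7-4 and 1695 or 1563 between the names.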
